A study of Danio rerio with 6 samples.

How the data were processed

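Gene expression was measured in 6 RNA libraries of sorted macrophages from zebrafish (Danio rerio) larvae, 3 of the cxcr3.2 mutant and 3 of the wild type. Groups and replicate numbers were taken from the sample titles, and the genotype field of the labels gives the same groups. Per the labels' protocols, larvae of a transgenic line with a farnesylated mCherry reporter under the mpeg1 promoter were dissociated in independent pools of 150 to 200, red cells were sorted, total RNA was extracted with a column kit, and cDNA was made and amplified with a low-input kit before single-read Illumina sequencing to about 10 Mreads. The age is 6 days in the characteristics and 5 days in the protocol, and this was left open. No label states a date, a batch or whether both genotypes were sorted on one day.

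The files hold raw read counts per Ensembl gene as deposited by the authors, 31962 genes for each library, with no normalization. Per the labels' protocols the reads were aligned to the GRCz10 genome, and the submitters' processing notes name Bowtie and TopHat without versions. The counting tool, its handling of multimapping reads and strand, and the annotation release are not given in the sources used here. 1 blank line in one file was skipped, and no row named anything other than a gene. Amplification without molecular identifiers and polyA priming of small inputs add noise that gene counts cannot separate from biological differences. Gene counts do not show the mutation itself. No genome was used here.

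Symbols were taken from a table of gene IDs and symbols, which named 26121 of the 31962 IDs and left 5841 without a symbol. Many of its symbols are upper-case orthologue names shared by several zebrafish genes, so that listed symbols were matched exactly, then regardless of case, then after removal of a paralog suffix, and symbols matching more than 3 IDs were dropped. IDs are printed where a symbol is shared or the gene is described at length. No chromosome position is given, since the position table used here is for another assembly.

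Total counts were 8452301, 8390293 and 6239470 in wild type replicates 1 to 3 and 9026853, 6792943 and 9607009 in mutant replicates 1 to 3. At these depths and with 3 libraries per genotype, precision was limited by the spread between libraries (common biological coefficient of variation 0.441). Replicates were compared before averaging, and no pair of one group agreed within sampling noise (chi-square per gene 18.3 or more), so that each was kept as a sample. The transcript of malat1 took 7.40% to 11.2% of counts, and the 10 most abundant genes 18.0% to 32.9%.

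Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16499, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit, glmQLFTest) was fitted with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are Wald errors of the log2 fold change using the quasi-likelihood variance, and intervals are 95% intervals. Levels are TMM-scaled CPM computed from the counts. For genes in the cxcr3 and MPEG1 groups, exact two-sided permutation tests of log CPM were run as well, which cannot go below 0.1.

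For 26 gene lists, fixed before the data were examined and including 10 of other cell types, limma 3.58.1 camera was run with a preset inter-gene correlation of 0.01, again with an estimated correlation, and beside fry, with adjustment over the lists. With the estimated correlation no list passed. fry, which does not compare a list with other genes, called 2 lists: vacuolar ATPase subunits (adjusted p = 0.0176) and antigen processing and presentation (adjusted p = 4.67e-05). The list counts adjusted over all tested genes and over the list alone come from the edgeR fit.

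Genes to be named were chosen by a rule fixed before the data were examined. It names cxcr3.2, its paralogs and the mpeg1 gene whatever their values, then the 12 genes with the lowest p in each direction among those called with a mean log2 CPM of at least 1, a symbol that is not a clone name and no overlap between the genotypes, and up to 4 members with the lowest p of each list described. Called members outside it (cxcl8a, il12a, ATF3 and JUND) and, in the closing section, the genes of families, IRAK3, actc1b and pvalb2 were named after their values were seen.

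The test was checked on simulated data, with counts drawn for 16499 genes at the real means and library sizes for the comparison of mutant with wild type and 15463 genes kept by the filter. Changed genes were drawn from those with a mean log2 CPM of at least 1, so the shares do not cover genes of lower expression. Of 100 genes changed 2-fold, 11% were called, and of 100 genes changed 4-fold, 49%. Median recovered log2 fold changes were 0.99 and 1.97, and 4 unchanged genes were called, 6.15% of the calls. DESeq2 called 35% and 66%. A changed list gave a camera p of 1.25e-10 and an unchanged list 0.901. The simulated genes were drawn independently of each other, so this does not test camera on correlated genes. The estimated correlation in the lists that passed with the preset was 0.049 (actin) to 0.63 (muscle).

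Alternatives were other scaling (RLE, upper quartile), no count filter or a stricter one (50 counts in at least 3 libraries), DESeq2 1.42.0, limma voom with quality weights, robust edgeR, the replicate number as a block, genes of other cell types left out before scaling, and each library left out in turn. Leaving out heat shock genes before scaling was added after the data were seen. A planned test of whether called genes lie on the chromosome of cxcr3.2 is given in the closing section.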

Results

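Macrophages were sorted by flow cytometry from zebrafish larvae carrying a red reporter driven by the promoter of mpeg1, a macrophage gene. Their polyadenylated RNA was sequenced after low-input cDNA amplification. The 6 libraries fell into 2 genotypes, homozygous cxcr3.2 mutant (3 libraries) and wild type (3 libraries). Each library came from its own pool of 150 to 200 larvae. The labels give the age as 6 days after fertilisation in one field and 5 days in another. Gene counts per library summed to between 6239470 and 9607009, and 16499 Ensembl genes had enough counts to be tested. The comparison of mutant with wild type asks which transcripts of unchallenged larval macrophages differ when the chemokine receptor gene cxcr3.2 is mutated. Fold changes are given as mutant over wild type throughout, and levels as TMM-scaled CPM with mean ± SD over 3 libraries.

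The cxcr3.2 transcript (ENSDARG00000041041), which encodes a receptor for CXC chemokines, was retained in the mutant and did not differ detectably between the genotypes. Its sign changed with the scaling. It measured 190, 155 and 175 CPM in the wild type libraries and 168, 204 and 154 CPM in the mutant libraries, that is 173 ± 17.8 CPM against 175 ± 25.8 CPM. Its log2 fold change was 0.01 (SE 0.16, 95% interval −0.35 to 0.38), with an adjusted p of 0.985 in edgeR's quasi-likelihood test and p = 1 in an exact two-sided permutation test, for which 0.1 is the smallest value possible with 3 libraries against 3. A gene-level count does not show whether the transcript carries the mutation, so this value neither bears out nor contradicts the genotype labels. Its paralog cxcr3.3 (ENSDARG00000070669) measured 57.3 ± 17.1 CPM in wild type and 32.3 ± 5.23 CPM in mutant macrophages (log2 fold change −0.83, SE 0.26, adjusted p = 0.195). A further paralog, named CXCR3 without a suffix in the name table (ENSDARG00000007358), measured 15.5 ± 3.9 CPM and 2.22 ± 2.03 CPM (log2 fold change −2.79, SE 0.73, adjusted p = 0.136). The 3 libraries of one genotype did not overlap those of the other for either paralog, and neither passed edgeR's test, whereas DESeq2 called CXCR3 (adjusted p = 0.0054, within a range of 0.0054 to 0.312 over all alternatives).

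**Figure D1:**
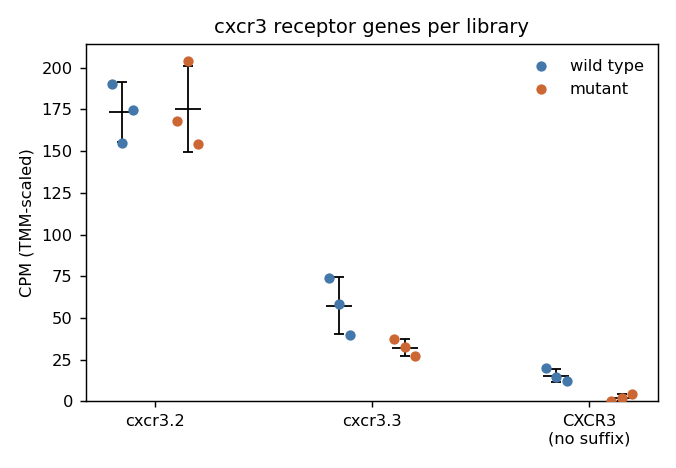
TMM-scaled CPM of the cxcr3 receptor genes in each library (points, vertical axis from 0), with mean and SD as bars, for wild type (blue) and mutant (orange). cxcr3.2 averaged 173 CPM in wild type and 175 CPM in mutant libraries, and all mutant libraries lay below all wild type libraries for cxcr3.3 and CXCR3, whose differences did not pass edgeR's test.

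Between the genotypes, 51 genes were higher and 146 lower in mutant macrophages at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). At least 2-fold differences made up 33 of the higher and 129 of the lower calls, and 35 of the lower calls differed by at least 8-fold, against 2 of the higher calls. Heat shock proteins and their co-chaperones accounted for 23 of the 146 lower calls. For each of the 197 genes called, the 3 mutant libraries did not overlap the 3 wild type libraries, which was the case for 20.6% of all tested genes where chance gives 10%. The first principal component held 30.3% of the variance and separated the genotypes. The counts depended on the number of libraries, the test, the count filter and the design. With any one library left out, 3 to 11 genes were higher (3 without wild type replicate 3) and 43 to 98 lower (43 without wild type replicate 3), and DESeq2 called 437 higher and 509 lower. A stricter count filter gave 142 higher and 295 lower, and a fit with the replicate number as a block 13 higher and 84 lower.

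Heat shock genes were among the lower genes. HSPB1, a small heat shock protein (ENSDARG00000041065), was 35.7-fold lower in the mutant (1198 ± 487 CPM in wild type, 33.8 ± 20.2 CPM in mutant, log2 fold change −5.16, SE 0.41, adjusted p = 0.00312). HSPH1, a nucleotide exchange factor of Hsp70 chaperones (ENSDARG00000019874), was 30.1-fold lower (log2 fold change −4.91, SE 0.31). The co-chaperones STIP1 (ENSDARG00000004906) and dnaja (ENSDARG00000051762) were 7.87-fold and 9.81-fold lower, and HSP90AA1 8.85-fold lower. The inducible chaperone gene hsp70l (ENSDARG00000055723) fell from 32990 ± 16680 CPM to 2390 ± 285 CPM, a 13.8-fold difference. Because reads of near-identical hsp70 copies can be assigned to one another, the single copies are uncertain; summed over 4 copies (hsp70.1, hsp70.3, hsp70l and a gene named HSPA2) they measured 133300 ± 67670 CPM in wild type and 14130 ± 1465 CPM in mutant macrophages, a 9.44-fold difference. In the fixed list of immediate early and heat shock genes, which tissue dissociation can also induce, 13 of 59 tested genes fell and none rose. Adjusted over the list alone, 24 fell and 2 rose. The list's median log2 fold change was −0.45 (camera with a preset correlation, adjusted p = 1.06e-17; adjusted p = 0.585 with an estimated correlation). The fall lay in the heat shock part (11 of 15 genes lower, median −3.05) more than in the immediate early part (2 of 44 lower, ATF3 and JUND, median −0.35), a division made after the values were seen.

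The heat shock genes also differed among wild type libraries. Those of the fixed list held 8.45%, 16.9% and 10.3% of all counts in wild type replicates 1, 2 and 3, and 2.68%, 2.66% and 2.89% in the mutant replicates. Immediate early genes of the list held 1.69% to 2.0% in all 6 libraries. Over all genes named as heat shock proteins or co-chaperones, the shares were larger, 12.2%, 23.9% and 14.7% in wild type replicates 1 to 3. They were 4.07%, 4.03% and 4.44% in mutant replicates 1 to 3. Without wild type replicate 2, the library with the highest share, 10 genes were higher and 60 lower, and the median of the heat shock part was −2.58.

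**Figure D2:**
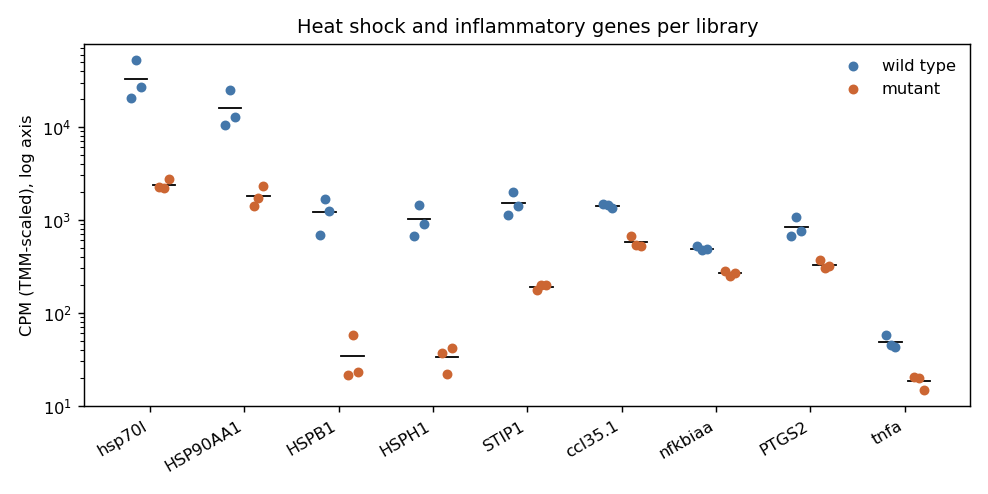
TMM-scaled CPM (log axis) of 9 heat shock and inflammatory genes in each library, with the mean of each genotype as a bar, for wild type (blue) and mutant (orange). The wild type libraries lay above the mutant libraries for every gene plotted, from 1.85-fold in nfkbiaa to 35.7-fold in HSPB1.

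Several lower genes of other functions ranked with the heat shock genes. The gene with the lowest p was ctss2.2, a cathepsin S protease gene (ENSDARG00000013771), which was 8.35-fold lower (133 ± 18.9 CPM in wild type, 15.9 ± 1.43 CPM in mutant, log2 fold change −3.06, SE 0.18, adjusted p = 0.00111). MINDY3, a deubiquitinase gene, was 15.8-fold lower, MLF1 13.5-fold lower, and RHBDD1, which encodes a rhomboid protease, 13.3-fold lower. ZFAND2B, whose product binds the proteasome, was 6.51-fold lower. The mitochondrial protein gene CHCHD2 was 4.4-fold lower and the kinase gene mknk1 3.34-fold lower. One further gene known only by a clone name ranked among the 12 lowest p in this direction. Each gene named in this paragraph was highest in wild type replicate 2, as the heat shock genes were, so it may not vary independently of them. RHBDD1 measured 132, 260 and 201 CPM in wild type replicates 1 to 3, and mknk1 311, 363 and 293 CPM. Of genes described below, SQSTM1, PTGS2 (ENSDARG00000004539) and PFKFB3 were also highest there, whereas ccl35.1, nfkbiaa, tnfa and PLIN2 were not.

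Among the 12 named genes with the lowest p that were higher in the mutant, DAB2, an endocytic adaptor gene (ENSDARG00000053091), was 2.61-fold higher (226 ± 46.8 CPM in wild type, 589 ± 17.7 CPM in mutant, log2 fold change 1.39, SE 0.16, adjusted p = 0.00709). The lysosomal protease gene ctsl.1 (ENSDARG00000003902) was 2.43-fold higher (393 ± 65.2 CPM against 955 ± 98.6 CPM, log2 fold change 1.28, SE 0.15). The apolipoprotein E gene apoeb (ENSDARG00000040295) was 2.07-fold higher (2415 ± 402 CPM against 4996 ± 482 CPM, log2 fold change 1.05, SE 0.13). ZNF827, a zinc finger protein gene, had the lowest p and was 2.84-fold higher. Transporter genes in this group were SLC22A8 for organic anions (21.7-fold, from 0.775 ± 0.372 CPM), SLC20A1 for phosphate (ENSDARG00000020114, 3.56-fold) and SLC36A1 for amino acids (2.79-fold). The cargo receptor gene TMED5 was 3.53-fold, NUS1 2.82-fold, NTMT1 2.57-fold, the oxysterol-binding protein gene OSBP2 2.44-fold and the ectonucleotidase gene enpp1 1.84-fold higher. One clone-named gene also ranked here.

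Of 42 tested inflammatory cytokine and mediator genes, 6 fell in the mutant and none rose, and 27 had a negative and 15 a positive sign; adjusted over the list alone, 13 fell and 1 rose. The chemokine gene ccl35.1 fell from 1413 ± 65.7 CPM to 576 ± 87.4 CPM (log2 fold change −1.29, SE 0.13, adjusted p = 0.00387). The prostaglandin synthase gene PTGS2 (ENSDARG00000004539) was 2.53-fold lower (adjusted p = 0.0139) and the cytokine gene tnfa 2.62-fold lower (adjusted p = 0.0299). The NF-κB inhibitor gene nfkbiaa was 1.85-fold lower (adjusted p = 0.0126). The remaining called members, cxcl8a and il12a, were 1.96-fold and 3.83-fold lower. The list's median log2 fold change was −0.32 (camera, adjusted p = 0.000143; adjusted p = 0.585 with an estimated correlation), and −0.16 without mutant replicate 3 (adjusted p = 0.0228). The heat shock share of the libraries differed between the genotypes in the same direction as these genes.

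The vacuolar ATPase list, the proton pump that acidifies lysosomes, was shifted upward as a group. Its 25 tested subunits had a median log2 fold change of 0.42, and 21 had a positive sign (camera, adjusted p = 2.68e-06; adjusted p = 0.494 with an estimated correlation). None of the subunits passed over all genes tested with edgeR, and 9 were higher adjusted over the list alone. ATP6V1H measured 82.3 ± 2.66 CPM in wild type and 135 ± 15.2 CPM in mutant macrophages (log2 fold change 0.71, SE 0.15, adjusted p = 0.0712), and ATP6V0B 265 ± 25.4 CPM and 435 ± 68.7 CPM (log2 fold change 0.72, SE 0.15, adjusted p = 0.0716). Lysosomal hydrolases and membrane proteins did not shift as a group (75 genes, median 0.19, camera adjusted p = 0.217). Among them ctsl.1 rose, and ctss2.2 and the phospholipase gene PLA2G15 (1.95-fold) fell; adjusted over the list alone, 2 rose and 3 fell. In the autophagy list (51 genes, median −0.02, mean −0.0074, camera direction up, adjusted p = 0.986), the cargo adaptor gene SQSTM1 was 2.39-fold lower (adjusted p = 0.0107) and RAB7A (ENSDARG00000021287), a GTPase of late endosomes, 1.86-fold higher (adjusted p = 0.0466), also when adjusted over the list alone.

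Genes of oxidative phosphorylation and of the actin cytoskeleton had small positive medians that passed camera with the preset correlation only, with no single member called. With fry the adjusted p was 0.16 and 0.1025. Splits that mixed the genotypes also passed 2 to 9 lists under this camera setting (closing section). Which lists passed there was not recorded. Passing this setting therefore does not by itself tie these shifts, or those of the lists above, to the genotype. The 76 oxidative phosphorylation genes had a median log2 fold change of 0.19 (camera, adjusted p = 0.000541; adjusted p = 0.607 with an estimated correlation), which was 0.11 without mutant replicate 2 (adjusted p = 0.023), the library in which muscle markers summed to 2224 CPM against 353 to 426 CPM in the others. The 65 actin and migration genes had a median of 0.15 (adjusted p = 0.00422; adjusted p = 0.585 with an estimated correlation). Adjusted over each list alone, 0 members passed in either. For single genes, actb1 had a log2 fold change of 0.40 (SE 0.093, adjusted p = 0.0867) and CORO1A of 0.45 (SE 0.13, adjusted p = 0.143). Among glycolysis genes (31 tested, median 0.13, adjusted p = 0.185), PFKFB3, which controls glycolytic flux, was 2.39-fold lower (adjusted p = 0.0152); adjusted over the list alone, 4 rose and 2 fell.

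Macrophage identity genes and effector lists did not shift as groups under camera. In the macrophage and microglia list (40 genes, median 0.15, mean −0.03, camera direction up, adjusted p = 0.376), apoeb and the myeloid transcription factor gene SPI1 (1.55-fold, adjusted p = 0.0487) rose, and ctss2.2 and slco2b1 (2.59-fold, adjusted p = 0.0404) fell; adjusted over the list alone, 10 rose and 5 fell. Of 3 genes named MPEG1, among which the reporter's own promoter gene could not be told apart, none was called: their log2 fold changes were −1.26 (ENSDARG00000043093, SE 0.29, adjusted p = 0.0904), −0.16 (ENSDARG00000055290, SE 0.17, adjusted p = 0.752) and −0.47 (ENSDARG00000078569, SE 0.56, adjusted p = 0.796). The first of these, MPEG1 ENSDARG00000043093, was called by DESeq2 (adjusted p = 0.00151) and under a stricter count filter (adjusted p = 0.0303), within a range of 0.00151 to 0.284 over all alternatives. In the oxidase and antimicrobial list (23 genes, median −0.16, adjusted p = 0.17), none passed over all genes, while 1 rose and 5 fell adjusted over the list alone; NCF1, an oxidase subunit gene, came closest (log2 fold change −0.80, SE 0.16, adjusted p = 0.0514). CALR fell (1.82-fold, adjusted p = 0.0457) in the antigen presentation list (28 genes, median −0.26, adjusted p = 0.124), where 0 rose and 3 fell adjusted over the list alone. For this list fry gave a downward shift (adjusted p = 4.67e-05), whereas camera with an estimated correlation gave an adjusted p of 0.585. In the lipid list (49 genes, median −0.03, adjusted p = 0.881), apoeb and the fatty acid binding protein gene FABP7 (ENSDARG00000034650, 3.11-fold) rose and PLIN2, which coats lipid droplets, fell 3.02-fold; 2 rose and 2 fell adjusted over the list alone. No member passed among chemokine receptors and CXC ligands (28 genes, median −0.20, adjusted p = 0.167), interferon response genes (29, median 0.01, mean 0.12, camera direction down, adjusted p = 0.986), complement genes (12, median 0.11, adjusted p = 0.368) or cell cycle genes (51, median −0.22, adjusted p = 0.185). Adjusted over the list alone, 1 chemokine system gene rose and 1 fell, 1 complement gene rose, and none passed in the other two.

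**Figure D3:**
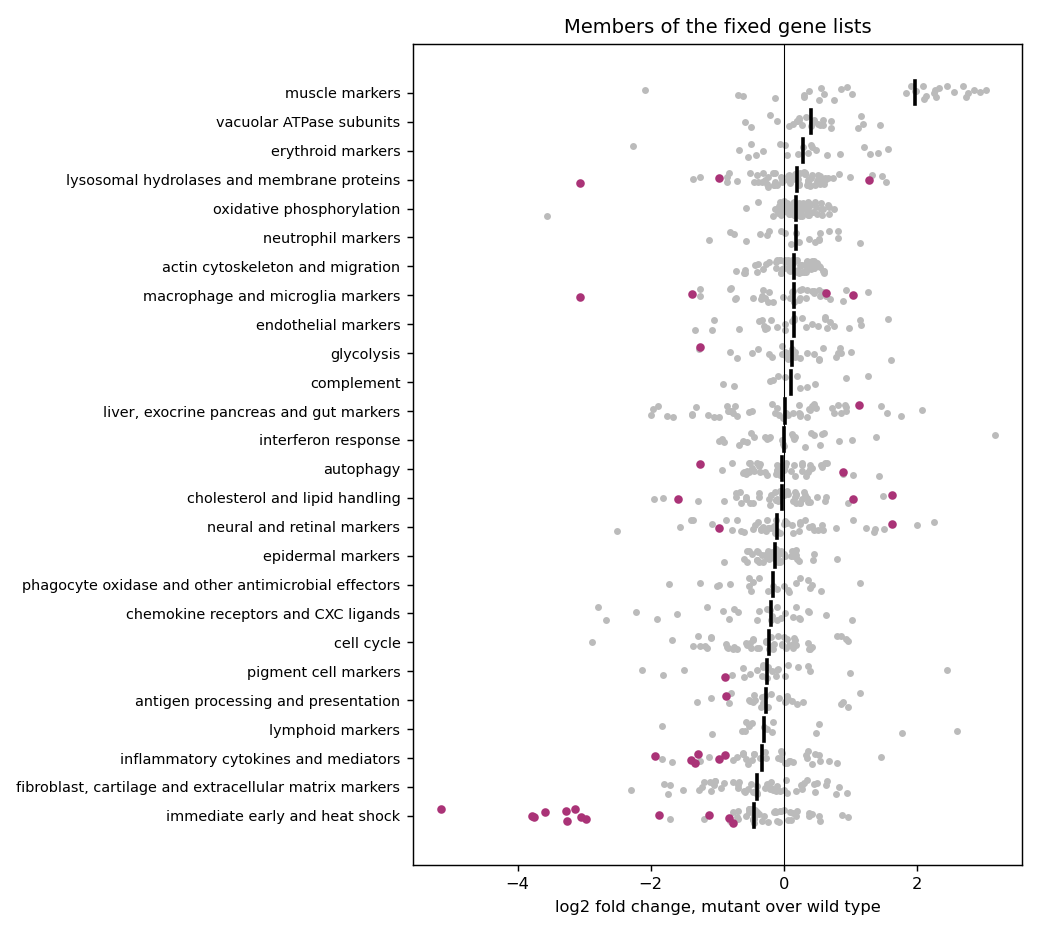
Log2 fold change (mutant over wild type) of every tested member of the 26 fixed gene lists, one list per line, with the list's median as a black bar and members called over all genes in purple. The immediate early and heat shock list had the lowest median (−0.45) and holds 13 called genes, and the muscle list had the highest (1.97), with none called.

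Markers of other cell types were compared between the genotypes, and the levels of epidermal markers show that the sorted pools were not macrophage RNA alone. The epidermal list summed to 8393 CPM in wild type and 7450 CPM in mutant libraries on average, with krt4 at 1535 and 1234 CPM. The neural and retinal list summed to 5921 and 4148 CPM. Of these, marcksl1b alone held 3572 and 1815 CPM, so this sum and its fall rest largely on 1 gene and do not show neural RNA. The macrophage and microglia list summed to 9953 and 13800 CPM, of which apoeb held 2415 and 4996 CPM. A called gene is therefore a difference between sorted pools and need not lie in macrophages. Muscle markers had a median log2 fold change of 1.97 over 33 genes (camera, adjusted p = 0.00153; adjusted p = 0.668 with an estimated correlation), with no member called over all genes or adjusted over the list alone. They summed to 2224 CPM in mutant replicate 2 and to 353 to 426 CPM in the other 5 libraries, and without mutant replicate 2 the median was −0.094 (adjusted p = 0.742). The creatine kinase gene ckma measured 8.24 ± 3.04 CPM in wild type and 54.3 ± 79.7 CPM in mutant libraries. None of the other 9 such lists passed camera: neutrophil (21 genes, median 0.19, adjusted p = 0.504), erythroid (21, 0.29, 0.217), lymphoid (15, −0.29, 0.229), epidermal (45, −0.13, 0.242), neural and retinal (51, −0.10, 0.986), pigment cell (25, −0.24, 0.217), digestive organ (52, 0.01, 0.524), endothelial (29, 0.15, 0.217) and fibroblast, cartilage and matrix markers (54, −0.41, 0.0718). The mean differed in sign from the median in the neural list (0.02, camera direction up) and the digestive list (−0.12, camera direction down). Called members were marcksl1b, a gene of a protein kinase C substrate (1.97-fold lower, adjusted p = 0.0057), and FABP7 in the neural list, TFEC in the pigment cell list (1.83-fold lower, adjusted p = 0.0184) and the transferrin gene tfa in the digestive list (2.2-fold higher, adjusted p = 0.0349). Adjusted over the list alone, 2 genes fell in the neutrophil list, 2 fell in the lymphoid list, 2 rose and 2 fell in the neural list, 1 fell in the pigment cell list and 1 rose and 1 fell in the digestive list, with none in the erythroid, epidermal, endothelial and fibroblast lists.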

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

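One alternative, leaving out heat shock genes before scaling, was chosen after seeing the data. The counts of 51 higher and 146 lower genes stayed within 1.5 times under RLE and upper quartile scaling, no count filter, voom, robust edgeR and both gene removals (52 to 73 higher, 125 to 166 lower), with 48 to 51 and 122 to 146 genes shared. They rose to 142 and 295 under the stricter count filter, which tests 9605 genes, and to 437 and 509 with DESeq2; the cause of the latter was not tested. With 1 library left out, and so fewer samples, 3 to 11 were higher and 43 to 98 lower. Of 42 named genes called, 18 to 28 stayed called with a library left out, 28 with the replicate block, and none reversed; RLE, the stricter filter, DESeq2 and robust edgeR kept all 42, and upper quartile scaling, no count filter and voom 40 or 41. Of those still tested, the gene removals kept all 38 and 35. 3 named-gene p-values that DESeq2 left undefined were not counted. The self-test above gives what 3 libraries per genotype can show for genes with a mean log2 CPM of at least 1. It called 11% of 2-fold changes, so that a gene not called may still differ.

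The labels number the libraries of both genotypes from 1 to 3, and a fit with the replicate block gave 13 higher and 84 lower genes, of which 10 and 79 were among the calls above. Same-numbered libraries did not deviate together (correlations −0.026, 0.0024 and −0.029), nor did each sample correlate best with its own number, so the numbers were not taken to pair the samples. The block changed the call of none of the 6 lists.

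With an estimated correlation 0 lists passed, and with fry 2, of which 1, vacuolar ATPase, is among the 6. Medians do not change with these tests (vacuolar ATPase 0.42, inflammatory −0.32, actin 0.15, oxidative phosphorylation 0.19, stress −0.45, muscle 1.97); adjusted p was 0.494 to 0.668 with an estimated correlation, and 0.104, 0.102, 0.16, 0.102 and 0.577 with fry for the last 5 of them in the order given. The median of the muscle list reversed to −0.094 without mutant replicate 2 (range −0.094 to 2.48 with a library left out). Across the other alternatives 5 to 9 lists passed. In all of these the 5 other lists passed camera in the same direction, but the inflammatory median moved to −0.16 without mutant replicate 3 and that of oxidative phosphorylation to 0.11 without mutant replicate 2. The muscle median moved to 0.96 under the stricter filter, 1.08 with voom and 0.95 with the replicate block. The cxcr3.2 log2 fold change, near 0 throughout, changed sign under upper quartile scaling (−0.0064), the stricter filter (−0.014) and with a library left out (range −0.10 to 0.11), with adjusted p of 0.866 to 0.993 over all alternatives. The lists were not run with DESeq2 or robust edgeR, as planned.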

Other observations

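The tests of gene families, of hsp70 copies, of single wild type libraries, of handling and genotype and of the gap of the vacuolar ATPase list to other genes, and the baseline condition on the debris test, were chosen only after the values they concern had been seen. Adjusted p-values of the families do not account for that choice, and some families hold genes already called. They describe the families and are not evidence of a shift. RAB GTPases, which direct vesicle traffic, tended to be higher in the mutant libraries. Of 62 tested members, 3 rose and none fell: RAB7A (ENSDARG00000021287, 1.86-fold), RAB10 (1.81-fold, adjusted p = 0.0247) and RAB1B (1.75-fold, adjusted p = 0.0224). The family's median log2 fold change was 0.15 (camera, adjusted p = 0.00253; adjusted p = 0.0468 with an estimated correlation, over 10 families). Proteasome subunits had a median of 0.24 over 53 genes with none called (adjusted p = 0.00253; adjusted p = 0.102 with an estimated correlation).

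Both tested peptidoglycan recognition protein genes fell, pglyrp5 from 159 ± 7.48 CPM to 62.4 ± 6.86 CPM (adjusted p = 0.00587) and pglyrp6 from 78.5 ± 38.7 CPM to 5.97 ± 2.47 CPM (adjusted p = 0.00845). Among 20 tested CCL chemokine genes, some of which the inflammatory list also holds, ccl35.1 included, 2 fell and none rose, ccl35.1 and ccl35.2 (2.55-fold, adjusted p = 0.00908); the family's median was −0.84 (camera, adjusted p = 4.2e-05; adjusted p = 0.0414 with an estimated correlation). IRAK3, which encodes a negative regulator of Toll-like receptor signalling, was 2.17-fold lower (adjusted p = 0.00975). Ribosomal protein genes (92, median −0.03, camera direction up, adjusted p = 0.929), mitochondrial mRNAs (13, 0.03, 0.929), TRiC chaperonin subunits (9, −0.10, 0.334) and solute carriers (275, 0.04, 0.137, with 4 higher and 3 lower) did not shift under camera. Ubiquitin-conjugating enzymes did (37, 0.17, 0.0454; adjusted p = 0.113 with an estimated correlation), and 2 of 26 endoplasmic reticulum chaperone genes fell, CALR and HSPA5 (median −0.12, adjusted p = 0.246).

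The heat shock genes of the fixed list, summed, were lower in each mutant library than in any wild type library. If each read was counted once, reads exchanged among the 4 near-identical hsp70 copies leave their sum as it is, and its log2 ratio was −3.24. The handling of multimapping reads is not known, so the sum does not exclude reads that were dropped or counted repeatedly. The 12 heat shock genes of the fixed list outside these copies had a median of −2.47 (quartiles −3.35 and −0.50), which an exchange among the 4 copies alone cannot give. A bound first set on all 89 named heat shock genes outside the copies, a median at or below −1, was not met (−0.38, 19 lower), and the narrower set was chosen after that value was seen. A single wild type library does not account for the difference either, since the median stayed at or below −2.58 whichever wild type library was left out. A difference in dissociation, temperature or sorting between the genotypes and an effect of the mutation itself cannot be told apart, because no label ties the sorts of both genotypes together: the lowest wild type library held 3.3 times the summed heat shock CPM of the highest mutant library (1.72 on the log2 scale), as either may give.

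Part of the remaining differences may follow the same stress gradient. The 123 genes lower in the mutant that are not heat shock genes were also higher in wild type replicate 2, the library with most heat shock RNA, than in the other wild type libraries (median difference 0.41 in log2 CPM, percentile 100 of 10000 random lists matched on expression). They were lowest in wild type replicate 1 (−0.32), which had the least. The difference was 0.04 for the inflammatory list and −0.06 for the genes higher in the mutant. Lists that were not called also lay past the 95th percentile of random lists of 123 genes (0.069, which shorter lists pass more easily), among them fibroblast (0.25), macrophage (0.25), lysosomal (0.19), neural (0.17) and lipid genes (0.12), and endothelial (−0.36) and digestive genes (−0.29) went the other way, so the percentile overstates how specific the difference is to the lower genes. The vacuolar ATPase shift may in principle be a composition effect of heat shock RNA filling the wild type libraries. Such an effect is one factor for all genes, and the median stood 0.44 above that of all other tested genes (lower quartile 0.23 above), which argues against it. This gap restates camera's comparison of the list with other genes and adds no separate evidence for the shift. Leaving out heat shock genes before scaling decided nothing, since it moved the list (to 0.42) and all genes by nearly the same step (0.0065 and 0.0067). Other explanations were not tested.

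Muscle genes were high in mutant replicate 2, where 27 of the 33 tested genes of the fixed list had their highest value and the most abundant, actc1b and pvalb2, reached 299 and 239 CPM. Muscle cells or their RNA in that sort may account for this, but the test left it open: of 35 tested muscle genes outside the fixed lists, chosen by symbol, 14 were highest there, fewer than the bound required, and their median log2 ratio to the other 5 libraries was 0.97 (quartiles −0.22 and 2.0), under the bound of 1. For unsorted debris of all larval tissues, the epidermal, neural and digestive lists had median log2 ratios of 0.03, 0.14 and 0.41 in this library. These lay under the bound of 0.5 set against debris, though the baseline condition kept the bound from deciding. The lists summed to 7529, 4194 and 2018 CPM there, against averages of 8000, 5202 and 2087 CPM in the other 5 libraries, while the muscle list gained 1841 CPM. Wild type libraries raise these averages (8393, 5921 and 2386 CPM). The mutant averages, this library included, were 7450, 4148 and 1765 CPM, so the library was not below its own genotype. These sums argue only against debris that raised these tissues by as many CPM as muscle. A smaller gain stays open, since digestive sums ranged from 1542 to 3786 CPM in the other 5 libraries and 21 of 52 digestive genes were highest in this library. No biological explanation was tested, as a single library is concerned.

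Of the 10 splits of the 6 libraries into groups of 3, the real one alone (1 of 10) called 51 or more genes in one direction and alone (1 of 10) called 146 or more; the highest of the others called 0 genes. For the lists, 3 of 10 splits, the real one included, passed 6 or more, and the highest of the others passed 9. Every other split passed at least 2 lists, so a list that passes camera with the preset correlation is not by that alone tied to the genotype. The splits are too few for a share under 0.05. A planned test of whether the called genes cluster on the chromosome of cxcr3.2, where variants linked to the mutant allele would lie, was void, because only 72.6% of the called genes (143 of 197) could be placed, under the 80% set for it. The bounds of that test were written after its result was seen.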
